A study of Canis lupus familiaris with 12 samples.

How the data were processed

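Peripheral blood RNA of German Shepherd dogs was sequenced, with 7 control and 5 osteoarthritis samples assigned by the disease state in the labels. Per the labels' protocols, blood was kept in RNAlater, RNA was isolated with a RiboPure-Blood kit, and unstranded paired-end libraries were sequenced together on a single NovaSeq lane. No step that removes globin RNA is mentioned there. Because the libraries carry no strand, reads of a gene and of an overlapping antisense gene cannot be told apart. The labels used here give no age, sex, treatment or batch, so no such term was available for the design.

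The submitters' processing notes name fastp 0.12.5, FastQC 0.11.7, HISAT2 2.1.0, featureCounts, Subread 2.0.1 and DESeq2 1.26.0, with the genome build CanFam3.1, and give no settings. The deposited values are regularized log2 (rlog) expression made by the authors, per the labels and the name of the table, with 1 column per sample and all 12 columns matched to samples by title. They range from -2.23 to 22.2 over 23284 genes. The transformation already scales samples to each other and shrinks genes with few reads towards their mean, so fold changes of such genes are understated. No counts were used here, depth per sample is unknown, and no count model was run.

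Genes carry the symbols of the table. Loci named by an NCBI gene number were given the current symbol where the reference gene table had a different one, which applied to 308 loci. That table belongs to the assembly UU_Cfam_GSD_1.0, not CanFam3.1, so it served only for names and for which genes neighbour each other.

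Genes with a mean rlog of at least 3 over all dogs were tested (12450). The main test was limma (version 3.58.1, in R 4.3.3) with a mean-variance trend, osteoarthritis minus control, without covariates, at a Benjamini-Hochberg adjusted p under 0.05. Gene lists fixed before the data were examined, 8 of cell type markers and 18 of pathways, were tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation and with fry beside it. A list needed 5 tested members. Each dog's mean over a cell type list was compared by an exact two-sided permutation test, adjusted over the 8 lists. The tests and the first group of alternatives were also chosen before the data were examined.

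Genes named in the text follow a rule set in advance. It took, per direction, the 10 genes with the largest difference among those that passed, filled up from the smallest unadjusted p where fewer than 10 passed, and only genes with a symbol. Since 0 passed, all of these are values that did not pass. It added up to 4 members with the smallest p of each list that passed in camera and up to 2 of each other list. Some genes that the rule takes are not reported here. Other genes are named as chosen after their values were seen.

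The gene test was tested on simulated data, drawn as normal values with each gene's mean and spread, and on the deposited values after the group means were removed, with 200 of the 12450 genes changed by known amounts in each of 10 repeats. The simulated genes were drawn independently of each other. In the simulated values limma recovered 48.2% of changes of size 0.5, 90.3% of size 1 and 99.1% of size 2 on the log2 scale. In the deposited values it recovered 38.7%, 94.8% and 99.8%. There the removal of group means left the added changes free of sampling error, so these rates are not the power in real data.

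Alternatives were no filter on low values, a mean rlog of at least 5, no mean-variance trend, a robust prior variance, centring of each dog on its median, quantile normalization, weights per dog (with statmod 1.5.0), exact Wilcoxon tests per gene, covariates for the balance of neutrophil and T cell markers and for genes that escape X inactivation, and leaving out each dog in turn. Chosen after seeing the data were a covariate for the erythroid marker level, a fit without the 3 dogs at the ends of the range of globin-locus levels, and list matching by the symbols in the table alone. Other splits of the 12 dogs into groups of 7 and 5 were drawn 100 times, the real one included. Figures were drawn with matplotlib 3.10.9.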

Results

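RNA sequencing of peripheral blood was used to ask whether gene expression differs between German Shepherd dogs with osteoarthritis, a degenerative joint disease, and control dogs of the same breed. The samples comprised 7 controls and 5 dogs with osteoarthritis, and the values are regularized log2 (rlog) expression for 23284 genes. A difference of 1 on this scale stands for a doubling, although the transformation shrinks differences of genes with few reads. Sequencing depth per sample is unknown, since rlog values keep no read totals, so no counting interval is given. Between any pair of samples, Pearson's r across genes lay from 0.966 to 0.992, where genes are not independent replicates. The labels do not state that each sample came from a separate animal, so p-values measure the spread between these 12 samples, called dogs here. Group values are means ± SD over 7 control and 5 osteoarthritis dogs.

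No gene passed the test between dogs with osteoarthritis and controls. Of 12450 genes tested, 0 were higher and 0 were lower in osteoarthritis at a Benjamini-Hochberg adjusted p under 0.05 in limma, and the smallest adjusted p was 0.685. At an unadjusted p under 0.05 there were 524 genes, 288 higher and 236 lower, where 622.5 would be expected by chance. An exact Wilcoxon rank sum test per gene also called 0 genes, with 499 at an unadjusted p under 0.05. The values of the 2 groups did not overlap for 17 genes, against 31.4 (0.253%) expected from chance arrangements of the dogs. The median absolute difference was 0.09 and the median half-width of the 95% interval was 0.27. In simulated normal values with 200 changed genes, limma recovered 90.3% of changes of size 1 and 48.2% of changes of size 0.5. In the deposited values with group means removed it recovered 94.8% and 38.7%, but there the added changes carry no sampling error. Neither rate is the power for a single changed gene. The simulated genes were drawn independently of each other, and in those runs 7.5 unchanged genes were called per repeat on average. Genes in these data are correlated, with a median estimated correlation of 0.22 within the lists tested below. In the real comparison 19 genes differed by at least 1, and 0 passed. The smallest p belonged to LOC106559235, an uncharacterized locus outside the rule for named genes and chosen after its values were seen, at 4.87 ± 0.31 in osteoarthritis and 5.76 ± 0.28 in controls.

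**Figure D1:**
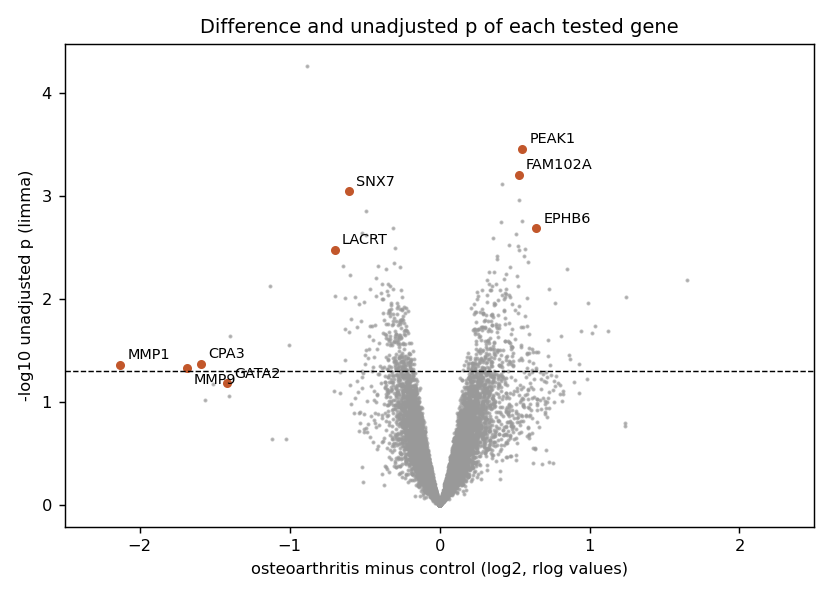
Difference between osteoarthritis (n = 5) and control (n = 7) dogs on the log2 scale (horizontal) against -log10 of the unadjusted limma p (vertical), with 1 point per tested gene (12450) and named examples in colour. The dashed line marks an unadjusted p of 0.05, and no gene passed after adjustment (smallest adjusted p 0.685).

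Among named genes above controls, the kinase family member PEAK1, which acts in cytoskeletal signalling, stood at 6.98 ± 0.14 in osteoarthritis and 6.43 ± 0.23 in controls, a difference of 0.55 (SE 0.12) or 1.47-fold. FAM102A differed by 0.53 (SE 0.12), from 8.08 ± 0.23 in controls to 8.60 ± 0.20. EPHB6, an ephrin receptor without kinase activity, differed by 0.64 (SE 0.17), and TPPP, a tubulin-binding protein, by 0.57 (SE 0.16). Values were also higher for IGSF3 (0.55), TBC1D16 (0.52), the endocannabinoid-degrading lipase MGLL (0.51), the transcription factor SOX13 (0.46), ATXN7L3B (0.41) and SAC3D1 (0.36). Each of these 10 genes lay above the control mean in 5 of 5 dogs with osteoarthritis, which their choice by smallest p favours. Each had an adjusted limma p of 0.937, so none is distinguished from the spread between dogs.

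Among named genes below controls, the sorting nexin SNX7 stood at 5.98 ± 0.28 in osteoarthritis and 6.58 ± 0.25 in controls, a difference of -0.60 (SE 0.15), or 1.52-fold lower. LACRT, whose protein product lacritin is known from tears, differed by -0.70 (SE 0.20), and the calcium channel subunit gene CACNB4 by -0.65 (SE 0.19). BCL2L15 (-0.60), the G protein subunit gene GNG10 (-0.52), MTERF1 of mitochondrial transcription (-0.34), C32H4orf3 (-0.31), SNW1 of splicing (-0.30), CCDC137 (-0.30) and PPCS of coenzyme A synthesis (-0.26) were also lower. These 10 genes had the same adjusted limma p of 0.937 and did not pass. MTERF1 lay below the control mean in 4 of 5 dogs and the other genes in 5 of 5, counts that the choice by smallest p favours.

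Whole blood is a mixture of cells, and marker lists of 8 cell types were compared. T cell markers were higher in osteoarthritis by a mean of 0.25, with 21 of 22 members higher, and erythroid markers by 0.46, with 19 of 21 members higher. The erythroid difference was 0.24 without osteoarthritis 4 and 0.28 without control 4. The eosinophil and basophil list was lower, with a mean difference of -0.64 and 8 of 10 members lower. Without CPA3, GATA2, FCER1A and IL3RA its mean difference was -0.16, with 4 of 6 members lower. IL5RA (0.23) and ALOX15 (0.03), named after their values were seen, were higher. Against other genes, with a preset correlation of 0.01 between members, camera gave adjusted p = 5.59e-06 for T cells, 5.42e-05 for erythroid cells and 0.00547 for eosinophils and basophils. All 3 calls were lost with an estimated correlation (adjusted p = 0.747 for each). No member of any of these lists passed over all genes, nor adjusted over the list alone (0 genes).

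The T cell example nearest to the threshold was the cytokine receptor IL7R, at 10.23 ± 0.33 in osteoarthritis and 9.84 ± 0.40 in controls. Next were THEMIS (difference 0.31), the transcription factor BCL11B (0.31) and the kinase ZAP70 (0.30). Among erythroid genes, the anion exchanger SLC4A1 stood at 9.03 ± 1.00 in osteoarthritis and 8.21 ± 0.81 in controls, a difference of 0.82. Differences were smaller for beta spectrin SPTB (0.63) and glycophorin C (GYPC, 0.57). Cytotoxic lymphocyte markers had 20 of 22 members higher and a mean difference of 0.15 (0.28 without control 4 and 0.08 without control 1), with adjusted p = 0.0298 in camera and adjusted p = 0.747 with an estimated correlation. Their examples were IL2RB (0.37), perforin PRF1 (0.50), NCR3 (0.23) and NCR1 (0.28).

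In the eosinophil and basophil list, IL3RA, the receptor chain for interleukin-3, stood at 5.94 ± 1.00 in osteoarthritis and 7.34 ± 1.21 in controls. Mast cell carboxypeptidase CPA3 stood at 6.72 ± 0.92 and 8.31 ± 1.75, transcription factor GATA2 at 5.39 ± 0.98 and 6.81 ± 1.72, and the IgE receptor chain FCER1A at 5.86 ± 0.52 and 6.86 ± 1.00. These are 2.63-fold, 3.01-fold, 2.67-fold and 2.01-fold lower means, each with an adjusted limma p of 0.937. The other 6 members of the list had a mean difference of -0.16. Neutrophil markers were lower in 15 of 20 members (mean difference -0.17, or -0.09 without MMP9, adjusted p = 0.0318) and B cell markers in 16 of 19 (mean difference -0.10, adjusted p = 0.0425). With a single dog left out, the neutrophil difference ran from -0.077 (without osteoarthritis 5) to -0.267 (without osteoarthritis 1). The B cell difference ran from -0.013 (without osteoarthritis 1) to -0.175 (without osteoarthritis 2). With an estimated correlation, adjusted p = 0.747 for both lists. Neutrophil examples were MMP9 (-1.69), the oxidase subunit NCF1 (-0.21) and the calcium-binding protein S100A12 (-0.28). B cell examples were BANK1 (-0.27), TNFRSF13C (-0.35) and CD22 (-0.21). Monocyte markers had 14 of 19 members lower (adjusted p = 0.149) and platelet markers 12 of 20 higher (adjusted p = 0.866), and neither list passed. The monocyte list was called lower without control 2 or 7 or osteoarthritis 1 or 3 (adjusted p down to 0.00908), and the platelet list higher without the 3 dogs at the ends of the globin range (0.0319), a setting chosen after seeing the data.

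**Figure D2:**
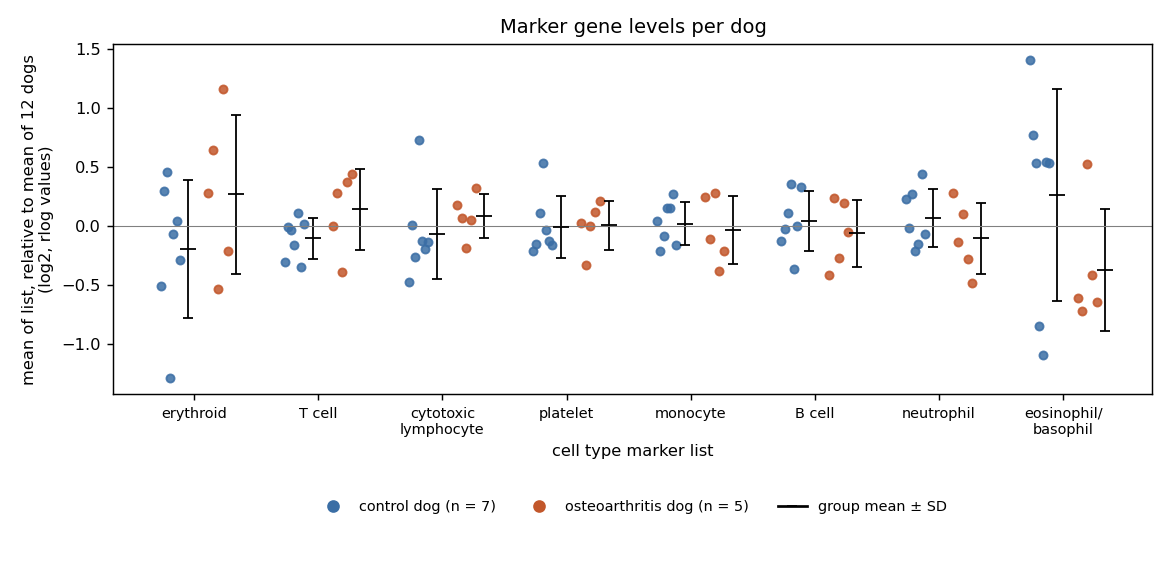
Mean rlog of each cell type marker list per dog, relative to the mean of all 12 dogs (vertical, log2), for 8 lists (horizontal), where each point is a dog and bars show group means ± SD (7 control, 5 osteoarthritis). The groups overlap in every list shown, and the smallest adjusted permutation p is 0.588.

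Each dog's mean over a list was also compared between groups by an exact two-sided permutation test over the 792 arrangements of the dogs. The smallest p that this test can reach is 0.0025 or less. Of the 8 cell type lists 0 passed, and the smallest adjusted p was 0.588. When a dog was left out the smallest adjusted p was 0.097 (T cells without osteoarthritis 3, difference 0.38) and 0 lists passed. T cell markers averaged 9.22 ± 0.34 in osteoarthritis and 8.97 ± 0.17 in controls (exact permutation p = 0.136). Erythroid markers averaged 8.91 ± 0.68 and 8.45 ± 0.59 (exact permutation p = 0.241), and eosinophil and basophil markers 7.47 ± 0.52 and 8.11 ± 0.90 (exact permutation p = 0.183). Neutrophil markers averaged 10.17 ± 0.30 and 10.34 ± 0.24 (exact permutation p = 0.294).

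The share of expression held by a few loci next to globin genes differed widely between dogs. The loci LOC100855540 and LOC100855558, which lie between HBQ1 and HBM in the reference assembly UU_Cfam_GSD_1.0, and LOC480784 and LOC609402, which lie near HBE1, made up 14.2% to 54.2% of summed expression (values returned from the log2 scale) per dog. Their share was 28.9% ± 9.74 in controls and 38.5% ± 11.1 in osteoarthritis (exact permutation p = 0.146). The mean level of these loci followed the first principal component, which held 28.7% of the variance, with r = 0.949 and rho = 0.972 over 12 dogs (permutation p = 1e-05 for each, the smallest that 100000 resamples can give). These loci and the erythroid markers were among the genes that the component was computed from, so the measures are not independent. Over the 14 relations computed, the adjusted p was 4.67e-05 for r and 0.00014 for rho, and r was 0.921 without the 2 dogs farthest from the median.

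Lists of immune pathways and of glycolysis had lower values in osteoarthritis in camera. Interferon response genes were lower in 24 of 27 members (mean difference -0.16, adjusted p = 0.00917 in camera, and adjusted p = 0.747 with an estimated correlation), among them IFIT3 (-0.36), the kinase EIF2AK2 (-0.48), ISG20 (-0.23) and SAMD9L (-0.19). The interferon list mean was highest in control 3 (9.42) and lowest in osteoarthritis 3 (7.90), and the call was lost without either. Its dog means gave an exact permutation p of 0.63. Toll-like receptor and inflammasome genes were lower in 18 of 24 (mean difference -0.12, adjusted p = 0.00913, and adjusted p = 0.747 with an estimated correlation), with TLR10 (-0.31), TLR3 (-0.55), TLR1 (-0.22) and the inflammasome adaptor PYCARD (-0.34). Genes of MHC class II antigen presentation were lower in 15 of 18 (mean difference -0.10, adjusted p = 0.0298, and adjusted p = 0.747 with an estimated correlation), with the protease CTSS (-0.32), RFXANK (-0.13) and DLA-DMA (-0.14), while CD80 differed by 0.13. Glycolysis and hypoxia genes were lower in 20 of 32 (mean difference -0.07, adjusted p = 0.00781, and adjusted p = 0.747 with an estimated correlation), with hexokinase HK3 (-0.34), enolase ENO1 (-0.36), the lactate transporter SLC16A3 (-0.30) and HIF1A (-0.24). The neutrophil minus T cell marker level of each dog averaged 0.95 ± 0.61 in osteoarthritis and 1.37 ± 0.38 in controls (exact permutation p = 0.165). With that balance as a covariate the interferon (adjusted p = 0.182), Toll-like receptor (0.539) and glycolysis (0.455) calls were lost, and the MHC class II call was kept (0.00111). With weights per dog the MHC class II call was lost (0.186), and the interferon list was not called and turned to the other direction (0.747). Without the 3 dogs at the ends of the globin range the MHC class II (0.782) and Toll-like receptor (0.134) calls were lost, and the interferon list again turned without a call (0.0799). With an erythroid covariate, chosen after seeing the data, the MHC class II (0.178) and Toll-like receptor (0.247) calls were lost, and with the X-linked covariate the interferon (0.679) and MHC class II (0.12) calls were lost. No member passed over all genes, nor adjusted over the list alone.

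Matrix proteases and their inhibitors, enzymes that act on cartilage and other matrix, were lower in 16 of 20 measured members (mean difference -0.27, adjusted p = 0.0298 in camera, and adjusted p = 0.747 with an estimated correlation). The median difference was -0.09, and without MMP1 and MMP9 the mean over the other 18 members was -0.08, so these genes make up most of the list mean. Collagenase MMP1 had the largest difference of all tested genes, at 8.95 ± 1.57 in osteoarthritis and 11.08 ± 2.23 in controls, or 4.38-fold lower. Gelatinase MMP9, also a member of the neutrophil list, stood at 9.76 ± 1.23 and 11.45 ± 1.81, or 3.22-fold lower. Both had an adjusted limma p of 0.937, and MMP1 and MMP9 lay below the control mean in 4 of 5 dogs with osteoarthritis. Control 4 and control 5 were as low as those dogs, at 8.14 and 7.83 for MMP1 and 9.13 and 8.85 for MMP9. Osteoarthritis 3, at 11.71 for MMP1 and 11.96 for MMP9, lay among the other controls. CTSS (-0.32) and the urokinase receptor gene PLAUR (-0.22) differed less. No member passed over all genes, nor adjusted over the list alone.

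**Figure D3:**
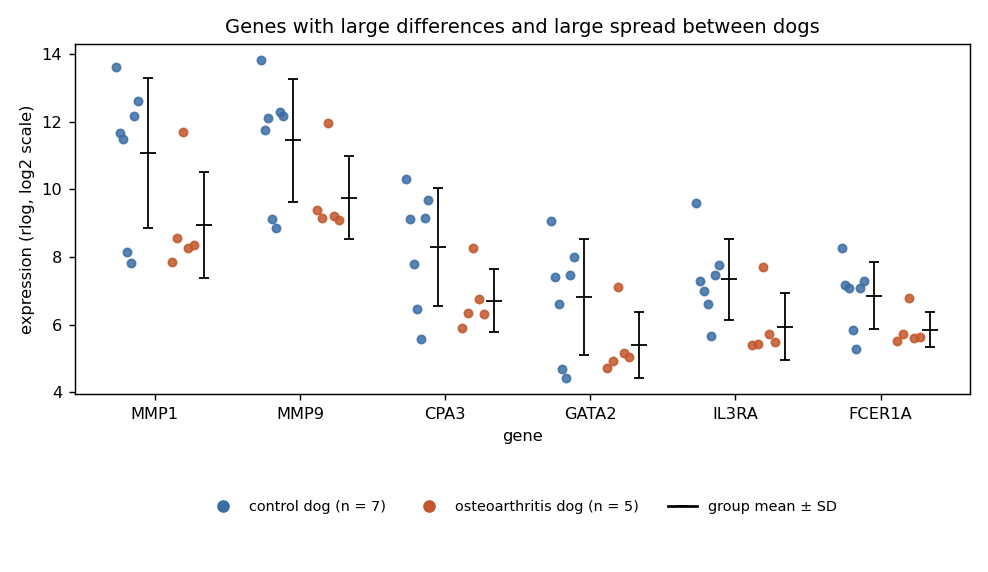
Expression (rlog, log2 scale, vertical) of 6 genes (horizontal) in each control (n = 7) and osteoarthritis (n = 5) dog, with bars for group means ± SD. For MMP1 the means are 11.08 in controls and 8.95 in osteoarthritis, and in each gene the ranges of the groups overlap.

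The remaining 13 pathway lists did not pass over all dogs. Calls given below for other settings used the preset correlation of 0.01 in camera. With an estimated correlation no list passed over all dogs (smallest adjusted p 0.747). Complement genes were lower in 11 of 15 (adjusted p = 0.0666), with the anaphylatoxin receptor C3AR1 at -0.55 and ITGAX at -0.24. This list was called without control 2, 4, 5 or 7 or osteoarthritis 1 (adjusted p down to 0.0133) and with no filter (0.0190). TGF-beta and BMP signalling genes were higher in 20 of 28 (adjusted p = 0.199), with TGFBR3 at 0.52 and LTBP3 at 0.35, and were called with the erythroid covariate (0.0244). Immediate early genes were higher in 16 of 23 (adjusted p = 0.279), with MAFF at -0.33 and NR4A1 at 0.44, and were called with the neutrophil minus T cell balance (0.00362). Wnt signalling genes were higher in 15 of 24 (adjusted p = 0.434), with AXIN2 at 0.40 and FZD6 at -0.30. Collagens and matrix proteins were higher in 9 of 14 (adjusted p = 0.434), with COL17A1 at -0.24 and the laminin gene LAMC1 at 0.25. Eicosanoid and prostaglandin genes were lower in 14 of 22 (adjusted p = 0.186), with phospholipase PLA2G4A at -0.36 and thromboxane receptor TBXA2R at 0.48, and were called without control 4 (0.0472). Inflammatory cytokine and NF-kB genes were lower in 15 of 24 (adjusted p = 0.396), with interleukin-1 beta (IL1B) at -0.30 and CCL5 at 0.51.

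Oxidative phosphorylation genes were lower in 34 of 57 (adjusted p = 0.109), with NDUFB5 at -0.35. This list was called without control 1, 4, 6 or 7 or osteoarthritis 2 or 4 (adjusted p down to 7.64e-05), with no filter (0.0162), with the erythroid covariate (1.91e-11) and without the 3 dogs at the ends of the globin range (0.0161). Cell cycle genes were higher in 30 of 43 (adjusted p = 0.141), with PCNA at -0.31, and were called without control 4 or 7 or osteoarthritis 1 or 5 (down to 0.00031). Cytosolic ribosomal protein genes were higher in 49 of 78 (adjusted p = 0.846), with RPS2 at 0.40 and RPL17 at -0.34. They were called higher without control 3 (4.42e-05) or osteoarthritis 1 (0.0236) and with the X-linked covariate (0.00879). They were called lower without osteoarthritis 4 (0.0017) and with the erythroid covariate (3.94e-12). Ribosomal proteins have many near-identical pseudogene copies, so single values for them are uncertain. The estimated correlations were 0.686, 0.521 and 0.912 for the oxidative phosphorylation, cell cycle and ribosomal lists. With these, camera over all dogs gave adjusted p of 0.879, 0.868 and 0.997. The dog means of these lists gave an exact permutation p of 0.987, 0.624 and 0.908. Osteoclast and bone remodelling genes were higher in 13 of 21 (adjusted p = 0.846), with OSCAR at -0.46 and NFATC1 at 0.13. Genes near human osteoarthritis association loci were lower in 13 of 25 (adjusted p = 0.846), with LTBP3 at 0.35 and DUS4L at -0.22. Heat shock and unfolded protein response genes were lower in 17 of 32 (adjusted p = 0.994), with HSF1 at 0.20 and HSPH1 at 0.31. For these last 3 lists the mean, the median and the camera direction differed in sign.

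The camera calls were 3 lists higher and 8 lower, while fry, which tests whether members move one way without comparing them with other genes, called 0 (smallest adjusted p 0.792), and 0 when either direction was counted (smallest adjusted p 0.851). The lists lower numbered 4 without control 3, 5 without osteoarthritis 2, 5 without osteoarthritis 4 and 4 without osteoarthritis 5. The T cell, erythroid, and eosinophil and basophil calls were kept whichever single dog was left out. The erythroid call was lost without the 3 dogs at the ends of the globin range, a setting chosen after seeing the data (adjusted p = 0.0909). The eosinophil and basophil call (0.470), the cytotoxic lymphocyte call (0.95) and the T cell call (0.719) were lost with the neutrophil minus T cell balance. That covariate holds the T cell markers themselves. It also holds MMP9, which was high in the same dogs as CPA3 and GATA2, so the eosinophil and basophil loss is not separate evidence on cell balance. Other calls depended on single dogs. The neutrophil call was lost without control 1, 3 or 6 or osteoarthritis 2, 4 or 5 (adjusted p up to 0.480), and the B cell call without control 3, 4 or 7 or osteoarthritis 1 or 3 (up to 0.582). The cytotoxic lymphocyte call was lost without control 1, 3, 6 or 7 or osteoarthritis 1, 2 or 5 (up to 0.278), and the interferon call without control 3 or 4 or osteoarthritis 3, 4 or 5 (up to 0.481). The MHC class II call was lost without control 3, 4 or 5 or osteoarthritis 3 or 4 (up to 0.182), and the matrix protease call without control 1 or 6 or osteoarthritis 2, 4 or 5 (up to 0.191). The Toll-like receptor call was lost without osteoarthritis 2 or 4 (up to 0.121) and the glycolysis call without osteoarthritis 2 or 5 (up to 0.0689). Some calls were also lost with other settings. The B cell call was lost with mean rlog of at least 5 (0.0814), quantile normalization (0.064), weights per dog (0.0849), the X-linked covariate (0.0746) and without the 3 dogs at the ends of the globin range (0.0856), and the cytotoxic lymphocyte call with no filter (0.0922). The neutrophil call was lost with weights per dog (0.175), the X-linked covariate (0.0795) and without those 3 dogs (0.134), and the matrix protease call with weights per dog (0.0674), the erythroid covariate (0.218) and without those 3 dogs (0.269). With the neutrophil minus T cell balance the neutrophil and matrix protease lists were not called and turned to the other direction (0.456 and 0.95).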

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

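Values of named genes, of the list means and of the globin-locus level were checked for a dog far from the rest of its group. Of 234 groups of dogs checked, 11 had such a dog, where chance gives about 11.7. The tests below were chosen after the results were seen, except the splits of the dogs. The test of globin level for the set of 6 genes was set before it was run. The set itself was chosen after its values were seen.

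The dog osteoarthritis 3 stood apart from the other dogs with osteoarthritis in 5 genes that differ widely between dogs. It had rlog 11.96 for MMP9 (others 9.09 to 9.39), 11.71 for MMP1 (others 7.86 to 8.58), 7.72 for IL3RA (others 5.39 to 5.72), 7.13 for GATA2 (others 4.72 to 5.17) and 6.78 for FCER1A (others 5.52 to 5.73). Its mean over the eosinophil and basophil list was 8.37 (others 7.13 to 7.43). These 5 genes were highest in the same 6 dogs, and IL3RA, GATA2 and FCER1A are members of that list. The flags for these genes and the list are therefore not separate events. The NFATC1 value of osteoarthritis 3 was 8.63, below the other dogs with osteoarthritis at 8.89 to 8.95.

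The dog control 4 had the highest PRF1 value of the controls, 8.59 (others 6.54 to 7.12), and the highest means of the cytotoxic lymphocyte list, 7.98 (others 6.78 to 7.26), and of the platelet list, 8.89 (others 8.14 to 8.46). The dog control 3 had an ISG20 value of 12.87 (others 11.63 to 12.11).

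The lower CPA3, GATA2, FCER1A, IL3RA, MMP1 and MMP9 in osteoarthritis had a mean difference of -1.54. This set was chosen after its values were seen, which favours a large difference. The other 6 measured members of the eosinophil and basophil list had a slope of 0.268 on the 6-gene mean (95% interval 0.118 to 0.418), which does not decide whether eosinophils and basophils dropped together, since the set had taken the members with the widest ranges (3.0 to 4.7 against 1.6 to 2.4). By its slope within groups, globin-locus level would add 0.0337 to the difference (95% interval -0.79 to 0.86), which is too wide to exclude a part, so the influence of globin RNA cannot be told apart. Chance stays open, since that whole list gave an exact permutation p of 0.183. A loss of both cell types therefore stays open, and so do a loss of basophils alone and a change with the disease, which were not tested.

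Globin-locus level ranged over 3.46 log2 units between dogs. Scaling between samples would remove a dilution of all other genes alike by globin RNA. These values therefore cannot show whether such a dilution occurred. At an unadjusted p under 0.05, 18.9% of genes outside the erythroid list followed globin-locus level. Permuted dogs gave a median of 3.88% and a 95th percentile of 12.5% (permutation p = 0.005). Varying amounts of RNA from immature red cells may contribute: within groups the ribosomal protein list mean had a slope of 0.359 (SE 0.062) on globin level and the erythroid list mean 0.685 (SE 0.067). ALAS2, an abundant gene of haem synthesis and a member of that list, ranged from 13.05 to 16.58. Of the 21 erythroid members tested 0 are in another list, and blood itself contains these cells. Disease as a source was not separated from this, since the groups overlapped.

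The 3 lists higher and 8 lower in camera, 11 of 26, do not exclude chance. Of 100 splits of the 12 dogs 33 gave as many lists, with 18 as the highest of the others. The preset correlation of 0.01 may be too low here, since the median estimated correlation over those 11 lists was 0.402. A count of 0 genes cannot be tested in this way, because 100 of 100 splits give at least 0 whatever the data, and the highest other split gave 31. For the 524 genes at an unadjusted p under 0.05, 45 of 100 splits gave as many, so that count does not exclude chance either. The highest other split gave 2278, which points to a structure among the dogs, whose source was not tested.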

How the results depend on the processing

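The count of 0 genes higher held in 24 alternatives with limma or exact Wilcoxon tests, the 0 lower in 23 of them, and the genes at an unadjusted p under 0.05 ranged from 341 (without osteoarthritis 4) to 1385 (no filter), with 1173 without osteoarthritis 3. The exception, chosen after seeing the data, left out the 3 dogs at the ends of the globin range and called 1 gene lower, APOC1 (difference -1.34, adjusted p 0.00466). Over all dogs APOC1 differed by -1.13 with an adjusted limma p of 0.937. The dogs left out held the highest and lowest APOC1 values of the controls (control 3 at 6.61, control 4 at 3.56). They also held the highest value in osteoarthritis (osteoarthritis 4 at 4.72). Leaving them out therefore narrowed the spread within groups, and the SE was 0.13 against 0.36 over all dogs. A link of APOC1 to globin level was not tested. No cell type mean passed in any alternative run, and 10 of 152 such values changed sign, in 2 lists (monocyte and platelet). The 3 lists higher were 0 with an estimated correlation and 0 with fry, and 2 to 4 when a dog was left out. The 8 lists lower were 0 with an estimated correlation, 0 with fry, 3 with weights per dog, 2 with the neutrophil and T cell balance as a covariate (B cell and MHC class II), 4 with the X-linked covariate, 3 without the 3 globin dogs, and 4 to 10 when a dog was left out. T cell, erythroid and eosinophil and basophil calls were kept in 12 of 12 such fits, glycolysis and Toll-like receptor in 10, and the others in 5 to 7.

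Direction reversed for the interferon list with weights per dog (adjusted p 0.747) and without the 3 globin dogs (0.0799). With the balance covariate, partly built from neutrophil genes, it reversed for the neutrophil (0.456) and matrix protease (0.95) lists. With the erythroid covariate, which holds the list's own level, it reversed for the erythroid list (0.981), and for the ribosomal list, which was then called (3.94e-12). The ribosomal list ranged from 4.42e-05 to 0.897 when a dog was left out, and was called in the reversed direction without osteoarthritis 4 (0.0017). Otherwise the cause was not tested. Of 275 values for called lists 185 kept the call, 85 lost it and 5 reversed, and of 375 for the other lists 32 gained a call, 30 in the same direction and 2 in the other, while 49 changed direction, in 10 of 15 lists. No named gene passed in any of 2149 values, and 1 changed sign (CD22 without osteoarthritis 3). Camera has no robust setting, so lists have no value there. Depth is unknown, so its limits could not be assessed.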

Other observations

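The tests in this part were chosen after the results were seen. Interferon response genes differed widely between dogs of both groups. The list mean ranged from 7.90 to 9.42, highest in control 3, control 4 and osteoarthritis 1 and lowest in osteoarthritis 3. ISG15, a ubiquitin-like protein induced by interferon, ranged from 6.36 to 9.71 and the antiviral MX1 from 6.20 to 9.34. The means were 8.60 ± 0.54 in controls and 8.45 ± 0.55 in osteoarthritis (exact permutation p = 0.63).

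Several genes outside the rule for named genes, chosen after their values were seen, had wide or split distributions. ESPN, an actin-bundling protein, lay between 9.33 and 10.19 in control 1, control 2, control 5, control 6 and osteoarthritis 5, at 7.61 in control 4, and between 5.47 and 6.43 in the other dogs. LOC106559672 lay between 11.09 and 12.01 in osteoarthritis 1, osteoarthritis 2 and osteoarthritis 4 and between 8.29 and 9.37 in the other 9 dogs. HPGD, which degrades prostaglandins, differed by -1.51 (SE 0.77), and it was high in the dogs with high CPA3. The eosinophil genes IL5RA (0.23) and CCR3 (-0.32) and the basophil gene MS4A2 (-0.34) differed less. None of these genes passed, with adjusted limma p of 0.937 or more.

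MMP9 fell into separate clusters of dogs. It lay between 8.85 and 9.39 in control 4, control 5 and the dogs osteoarthritis 1, 2, 4 and 5, and between 11.75 and 13.83 in control 1, 2, 3, 6 and 7 and osteoarthritis 3. MMP9 is usually abundant in neutrophils, and a hypothesis is that it followed basophil-type genes in these samples. CPA3 split the dogs in the same way (7.80 to 10.31 against 5.59 to 6.75), as did GATA2 (6.61 to 9.07 against 4.42 to 5.17) and MMP1 (11.49 to 13.63 against 7.83 to 8.58). The same 6 dogs were highest for 6 of 10 measured members of the eosinophil and basophil list, for 0 of 19 other neutrophil markers, and for 0.643% of all other tested genes. Neutrophil markers shared 2 to 5 of the 6 dogs. MMP9 may therefore follow basophil-type genes more than neutrophil markers. This stays a hypothesis, since the count of shared dogs and its bound were set with these overlaps already seen, after r within clusters had not decided it, and the cells that carry the transcript were not measured. No pooled r is given because of the clusters. Among the 6 dogs with higher MMP9, r with CPA3 was 0.680 (exact permutation p = 0.139, adjusted over 14 relations 0.278) and rho was 0.714 (exact permutation p = 0.136, adjusted 0.238). Among the other 6, r was 0.358 (exact permutation p = 0.487, adjusted 0.682) and rho 0.371 (exact permutation p = 0.497, adjusted 0.580). Without the 2 dogs farthest from the median of CPA3, r was 0.379 and 0.792. With the mean of the other neutrophil markers, r was 0.12 (exact permutation p = 0.806, adjusted 0.872) and 0.513 (exact permutation p = 0.282, adjusted 0.439), and rho was 0.429 in both (exact permutation p = 0.419, adjusted 0.534), with r of 0.208 and -0.576 without the 2 farthest dogs. With MMP1, r was 0.909 (exact permutation p = 0.025, adjusted 0.0583) and 0.0997 (exact permutation p = 0.865, adjusted 0.872), rho was 0.771 (exact permutation p = 0.103, adjusted 0.206) and 0.143 (exact permutation p = 0.803, adjusted 0.803), and r without the 2 farthest dogs was 0.573 and -0.886. Because the clusters were cut on MMP9 itself, these r values within them do not bear on the split.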
